A study of Mus musculus and Homo sapiens with 176 samples.

How the data were processed

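RNA was measured by sequencing in 8 libraries of nuclei from the cerebellum and prefrontal cortex of 1 mouse. Per the labels' protocols, frozen cerebellum of C57BL/6 mice was homogenized, nuclei were pelleted by ultracentrifugation through sucrose and stained for NeuN, and NeuN+ and NeuN- nuclei were sorted, so the RNA is that of nuclei and of what adhered to them. How prefrontal cortex was dissected and treated is not given in the sources used here. Replicate numbers come from the sample titles, which do not say what replicates 1 and 2 share.

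The deposited values are FPKM, fragments relative to transcript length and to the mapped fragments of the library, in gene-level Cufflinks tables, per the file headers. The submitters' processing notes name Trim Galore 0.3.7, TopHat2 2.1.1, Bowtie 1.1.1, Bismark, Cufflinks and the mouse build mm9, without giving their roles; the Cufflinks version, the gene annotation and the use of strand are not given in the sources used here. FPKM divides by library size and transcript length before deposit, so the values cannot be used as counts. FPKM of short RNAs are imprecise, and a gene that overlaps another can take its fragments. Each table lists 24854 features with 24318 symbols, positions, FPKM with confidence limits and a quantification status, and its length column is empty. The status was not OK for 14 values, among them Malat1, listed at 0 with a warning of too many fragments in 6 libraries; an exact 0 in these tables can therefore be a failed estimate, and such values are reported only as listed at 0. Coordinates are those of the tables, on mm9, with 1 added to the start. Gene types were taken from a RefSeq table of GRCm38.p6, with 23576 features matched by symbol, 1165 by synonym and 113 unmatched, and none of its coordinates were used.

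The FPKM of each library were multiplied by a median-of-ratios factor computed over 9109 features with at least 1 FPKM in all 8 libraries; the factors ran from 0.878 to 1.05. Features with at least 1 FPKM in at least 2 libraries were kept (14376), and log2(scaled FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, the variance trend on and 4 residual degrees of freedom. The pseudocount of 1 understates the changes of low genes. The 5 comparisons were NeuN+ against NeuN- in each region, cerebellum against prefrontal cortex in each gate, and the difference of the gate changes between the regions. Tests were two-sided and calls were made at a Benjamini-Hochberg adjusted p under 0.05 within a comparison.

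Before the data were examined, 27 gene lists were fixed for neuronal and glial cell types, cells of vessels, meninges, choroid plexus and blood, regional transcription factors, receptors and channels, immediate early genes, cholesterol synthesis, histone mark enzymes, nuclear long RNAs and handling stress; 26 had at least 5 kept members and were tested. The list of messages of the mitochondrial genome had 0 features in the tables and was not tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation. The directional test of fry asks whether a list's genes move, on balance, one way, and does not compare the list with other genes. Of the lists called by camera, 3 held with an estimated correlation, all in prefrontal cortex (astrocyte, microglia and voltage-gated channel genes). The estimate was below 0.01 for some lists that lost the call, such as glutamate receptor genes (-0.0317). A higher correlation is therefore not the reason for every loss.

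Also before the data were examined, the rule for named genes was fixed: per comparison, the 10 features with the largest positive and the 10 with the largest negative log2 change among those called, with a mean of at least 5 scaled FPKM in the higher group (for the difference between the regions, in the highest group), the same direction in every pairing of libraries (not for the difference between the regions) and no predicted, small RNA or clone symbol, together with up to 3 members of each list in its main direction and up to 2 in the other, with at least 1 FPKM, and Rbfox3. The rule's length condition could not be applied. After the values were seen, features with a status other than OK were also left out of the first part, which removed only Malat1, in 3 comparisons. Rnu12 and Rpph1 are small RNAs that the symbol patterns did not catch. Snap25 in the prefrontal comparison was named after its values were seen.

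Low values and their confidence limits were read for depth: 53.6% to 57.4% of the fragment numbers under 20 that they imply came within 0.05 of a whole number, so fragments were not recovered and no count test was run. In simulated data with 14376 genes at their real mean levels and the noise of the replicates, limma recovered in the prefrontal gate comparison 74% of genes above 5 FPKM changed 1.25-fold and 100% of those changed 1.5-fold, 2-fold and 4-fold (50 genes each), and called 18 of 14156 unchanged genes, with 0, 14 and 0 in the other comparisons of 2 groups. A shifted list was found by all 3 list tests, and 0 of 25 unshifted lists were called. The simulated noise was independent between genes and the same in all groups at a given level, and few genes were changed. The real replicates differed more in prefrontal NeuN- (median absolute log2 difference 0.0993) than in the other groups (0.0768 to 0.0826). The simulation therefore does not show how the list tests behave with correlated genes or broad changes. Nor does it show how limma calls behave where the groups differ in noise.

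Alternatives planned beforehand were unscaled FPKM, quantile normalization, FPKM rescaled to a common sum, a pseudocount of 0.1, no filter, a filter at 5 FPKM, features with status OK only, no variance trend, the replicate number as a block, each library left out in turn and, for comparisons of 2 groups, only their 4 libraries. An alternative without small RNAs, and the same settings for Rbfox3, were added after seeing the data. The chromatin samples were left out because no table for them was used here. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.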

Results

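The series profiled histone marks and RNA in nuclei sorted from mouse cerebellum and prefrontal cortex, to compare neuronal and glial nuclei within and between the regions. The nuclei were sorted on NeuN, the neuronal nuclear antigen encoded by Rbfox3. Sorting on NeuN aims at neuronal nuclei in NeuN+ and glial nuclei in NeuN-, although some neurons stain weakly. General neuronal messages were also present in the NeuN- libraries. By the list median they stood at 86.3% of their NeuN+ level in prefrontal cortex and 58.5% in cerebellum. The prefrontal share depends on library scaling: the median log2 change of all features there ran from -0.19 to 0.17 over 4 scalings. Gene expression values were used here for 8 RNA libraries from 1 C57BL/6 mouse (mouse 3) aged 8 to 10 weeks. They form 4 groups with 2 libraries each: prefrontal NeuN+, prefrontal NeuN-, cerebellar NeuN+ and cerebellar NeuN-. Because all 8 libraries came from the same animal, the p-values below measure the spread between libraries, which may be technical, and not the spread between mice. The chromatin immunoprecipitation samples of the series, 114 from mouse and 54 from the human lymphoblastoid cell line GM12878, were not analysed here.

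The FPKM summed to 307198 and 305653 in the prefrontal NeuN+ libraries, 426851 and 414230 in prefrontal NeuN-, 290314 and 291064 in cerebellar NeuN+, and 289350 and 292215 in cerebellar NeuN-. Between 11256 and 12494 features reached 1 FPKM in a library. Low FPKM values and their confidence limits put the sequencing depth of the libraries at roughly 1 to 1.52 times that of the shallowest, prefrontal NeuN+ replicate 1; the absolute depth is unknown. The 2 libraries of a group had Spearman correlations of 0.972 to 0.977 across 14376 kept features, against 0.680 to 0.808 for libraries of different groups. Features are not independent replicates, so these correlations describe the libraries only. The libraries of a group held 0 identical values above 0.

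Rbfox3, the gene of the sorting antigen, was listed at 16.2 and 15.7 FPKM in the prefrontal NeuN+ libraries and at 14.2 and 12.3 in prefrontal NeuN-. In the cerebellum it stood at 123 and 119 FPKM in NeuN+ and at 33.3 and 34.5 in NeuN-. After scaling, its NeuN+ level was 1.39-fold higher in prefrontal cortex (limma adjusted p = 5.5e-04; log2 change 0.47, and 0.25 to 0.71 under the other scalings) and 3.51-fold higher in cerebellum (limma adjusted p = 1.3e-06). The gate change was larger in cerebellum by 1.34 on the log2 scale (SE 0.0892, limma adjusted p = 3.3e-05). Below, group levels are means of scaled FPKM ± SD (n = 2), and folds are on the scale of FPKM + 1. Genes named for large changes are those that passed the naming rule, which leaves out most small RNAs, predicted genes and Malat1.

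**Figure D1:**
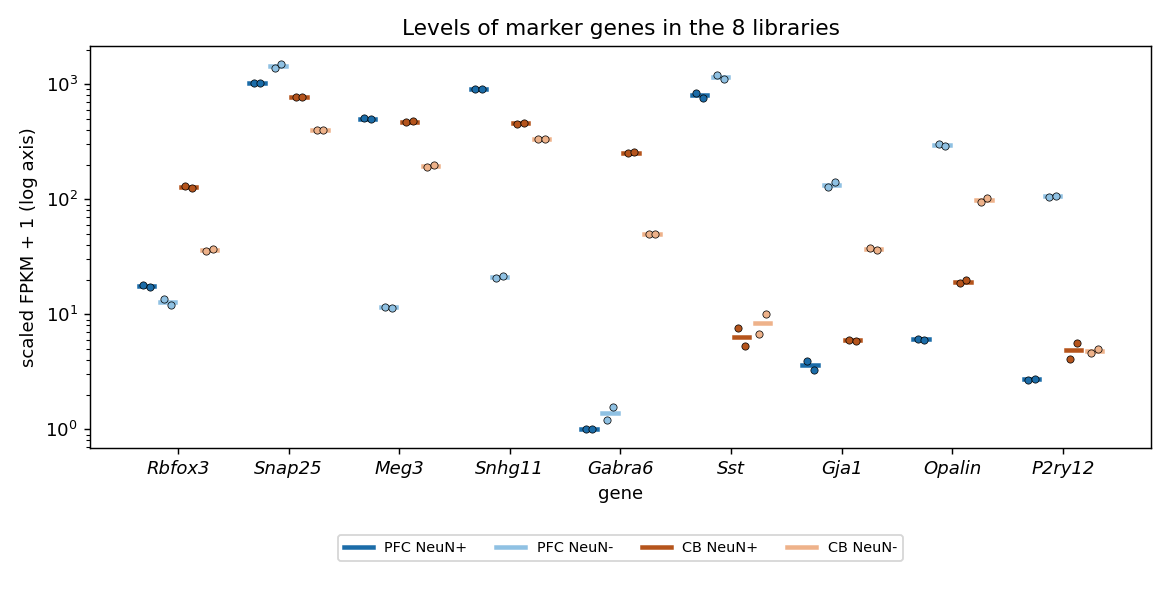
Scaled FPKM + 1 (log axis) of 9 marker genes in the 8 libraries, with 1 point per library and a bar at each group mean; PFC is prefrontal cortex and CB is cerebellum. Snap25 stood at 1439 ± 74.1 in prefrontal NeuN- libraries and at 1024 ± 3.43 in prefrontal NeuN+, while P2ry12 stood at 105 ± 2.04 in prefrontal NeuN- and at 3.82 ± 0.30 in cerebellar NeuN-.

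The comparison of NeuN+ with NeuN- nuclei in prefrontal cortex asked which genes separate the gates there. Glial genes were lower in NeuN+. Cyp27a1, a mitochondrial sterol hydroxylase (chromosome 1, 74760148 to 74784464, mm9), stood at 1.19 ± 0.20 in NeuN+ and 189 ± 14.6 in NeuN- (SD, n = 2), 86.6-fold lower. The myelin gene Opalin was 48.8-fold lower, at 5.07 ± 0.0998 against 295 ± 10.9, the microglial purinergic receptor gene P2ry12 38.9-fold lower and Gja1, which encodes the astrocytic gap junction protein connexin 43, 37.5-fold lower. Among genes higher in NeuN+, Hook1, a microtubule adaptor gene (chromosome 4, 95634070 to 95690965, mm9), stood at 91.4 ± 1.32 against 0.350 ± 0.0913, 68.5-fold higher. The noncoding RNAs Meg3 and Snhg11 were 43.7-fold and 43.0-fold higher, at 501 ± 2.89 against 10.5 ± 0.0644 and 910.3 ± 4.45 against 20.2 ± 0.627.

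The other genes with the largest increases in prefrontal NeuN+ were Kalrn (18.6-fold), which encodes a synaptic exchange factor, the imprinted noncoding RNA Ipw (17.6-fold), the ephrin receptor gene Epha10 (17.2-fold), Pip5kl1 (16.4-fold), the obligatory NMDA receptor subunit gene Grin1 (16.02-fold) and the potassium channel gene Kcnh7 (15.6-fold). Frmpd3 stood at 20.6 ± 1.39 in NeuN+ and was listed at 0 in both NeuN- libraries. The other large decreases were in Lpar6 (82.6-fold), a lysophosphatidic acid receptor gene, Neat1 (55.7-fold), the noncoding RNA of paraspeckles, Tmem63a (46.6-fold), Hapln2 (42.2-fold), which encodes a matrix link protein of myelinated axons, Plcd4 (39.0-fold) and Litaf (37.4-fold). The largest limma adjusted p among these 20 genes was 1.5e-06.

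Every tested member of 3 glial lists was lower in prefrontal NeuN+. All 19 astrocyte genes fell (list median log2 -3.16, camera adjusted p = 1.8e-10, adjusted p = 0.0305 with an estimated correlation), with the glutamate transporter gene Slc1a3 29.6-fold lower and Atp13a4 36.9-fold lower. All 19 microglial genes fell (median -3.70, camera adjusted p = 3.0e-09, adjusted p = 0.0305 with an estimated correlation), with the growth factor receptor gene Csf1r 23.3-fold lower. All 19 oligodendrocyte genes fell (median -3.86), including Aspa (22.9-fold) and Mal (21.6-fold), with camera adjusted p = 1.8e-10, adjusted p = 0.0613 with an estimated correlation. Of 12 precursor genes, 10 were lower, such as the growth factor receptor gene Pdgfra (13.8-fold), and 2 were higher, including Xylt1 (2.26-fold; camera adjusted p = 0.00378, adjusted p = 0.0992 with an estimated correlation). Bergmann glia genes had 2 higher, 8 lower and 2 not passing of 12; Lcat was 17.2-fold lower, and the AMPA receptor genes Gria1 and Gria4 were 2.58-fold and 2.35-fold higher (camera adjusted p = 0.0223, adjusted p = 0.140 with an estimated correlation). This list lost its call without library scaling and with the stricter filter. The 8 meningeal fibroblast genes were all lower (camera adjusted p = 0.00293, adjusted p = 0.120 with an estimated correlation), and 5 of 9 vascular genes were lower and 4 did not pass (camera adjusted p = 0.0165, adjusted p = 0.185 with an estimated correlation).

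Voltage-gated channel and glutamate receptor genes were mostly higher in prefrontal NeuN+. Of 27 voltage-gated channel genes, 23 were higher, 1 was lower and 3 did not pass (camera adjusted p = 2.6e-07, adjusted p = 0.0305 with an estimated correlation); the sodium channel gene Scn1a was 4.67-fold higher. Of 16 ionotropic glutamate receptor genes, 14 were higher, with the NMDA receptor genes Grin2a (12.4-fold) and Grin2b (5.40-fold) among them, and 2 were lower, with Grin2c 17.8-fold lower (camera adjusted p = 2.2e-04, adjusted p = 0.0613 with an estimated correlation). The 17 cortical projection neuron genes had 10 higher, 0 lower and 7 not passing, led by the kinase gene Camk2a (5.98-fold; camera adjusted p = 0.00960, adjusted p = 0.126 with an estimated correlation). Synaptic vesicle genes had 11 higher, 1 lower and 5 not passing of 17, with Syn1 1.47-fold lower (camera adjusted p = 0.00687, adjusted p = 0.308 with an estimated correlation). Nuclear long RNAs had 7 of 8 higher and 1 lower (camera adjusted p = 8.5e-04, adjusted p = 0.0865 with an estimated correlation). The count includes Malat1, which is listed at 0 with a quantification warning in the 6 libraries outside prefrontal NeuN+ and is given no value for that reason; the list kept its camera call here and for the difference between the regions when features with such warnings were left out. Of 13 GABA-A receptor genes, 9 were higher, including Gabrd (2.81-fold), and 2 were lower, including Gabrg1 (4.56-fold; camera adjusted p = 0.0468, adjusted p = 0.176 with an estimated correlation). GABA-A receptor genes lost the camera call when prefrontal NeuN+ replicate 1, prefrontal NeuN- replicate 1 or prefrontal NeuN- replicate 2 was left out (list medians 0.34, 0.48 and 0.30), and under 5 other settings.

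General neuronal genes did not pass as a list in prefrontal cortex (camera adjusted p = 0.173): of 19 genes, 9 were higher, 6 lower and 4 did not pass. Elavl2 was 2.97-fold higher, while the growth cone gene Gap43 and the neurofilament gene Nefm were 1.45-fold and 1.41-fold lower. The remaining lists did not pass with camera either (adjusted p in parentheses). Cortical interneuron genes had 7 higher, 1 lower and 6 not passing (camera adjusted p = 0.0723), with Gad2 2.24-fold higher. Granule cell genes had 2 higher, 9 lower and 5 not passing (0.129), Purkinje genes 6 higher, 4 lower and 4 not passing (0.341), and cerebellar inhibitory interneuron genes 6 higher, 2 lower and 3 not passing (0.132). Forebrain transcription factors had 7 higher, 1 lower and 3 not passing (0.0590), hindbrain transcription factors 0 higher, 4 lower and 7 not passing (0.264), and immediate early genes 5 higher, 2 lower and 3 not passing (0.0784), with Fos 2.73-fold higher. Histone mark enzyme genes had 13 higher, 5 lower and 7 not passing (0.115), cholesterol synthesis genes 2 higher, 9 lower and 5 not passing (0.109) and heat shock genes 1 higher, 4 lower and 2 not passing (0.191). Choroid plexus and ependymal genes had 1 higher, 4 lower and 2 not passing (0.291), and red blood cell genes 0 higher, 4 lower and 3 not passing (0.0518). Adjusted over the list alone, 24 of the 26 lists had the same counts; synaptic vesicle genes had 2 lower and cortical interneuron genes 0 lower.

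Across all features, limma with Benjamini-Hochberg adjustment called 10431 of 14376, with 5028 higher and 5403 lower in prefrontal NeuN+, of which 1353 and 1927 changed by at least 2-fold. The higher share was 48.2% with the scaling used, 36.0% with unscaled FPKM, 55.4% with quantile normalization and 59.97% with FPKM rescaled to a common sum; the median log2 change of all features was -0.01, -0.19, 0.08 and 0.17. Values of Hook1, Meg3, Ipw, Epha10, Grin1, Lpar6, Plcd4 and P2ry12 are uncertain because these genes overlap other features and the use of strand in counting is not given in the sources used here.

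The same comparison in cerebellum asked which genes separate the gates there. Stap2, an adaptor protein gene (chromosome 17, 56136499 to 56145029, mm9), stood at 126 ± 2.54 in NeuN+ and 5.23 ± 0.0953 in NeuN- (SD, n = 2), 20.4-fold higher. Grin2c, the NMDA receptor subunit gene of mature granule cells, was 8.60-fold higher, at 137 ± 0.157 against 15.0 ± 0.438. Among genes lower in NeuN+, Vtn, which encodes the matrix protein vitronectin (chromosome 11, 78312622 to 78315827, mm9), stood at 0.216 ± 0.205 against 52.7 ± 3.46, 44.4-fold lower. The GABA-A receptor gene Gabrb1 was 30.4-fold lower, at 3.17 ± 0.331 against 125 ± 1.37.

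Other large increases in cerebellar NeuN+ were in the phosphatase gene Ptpn22 (15.8-fold), Ltbp2 (13.5-fold), the interleukin receptor gene Il20rb (12.6-fold), the ephrin receptor gene Epha3 (9.64-fold) and the cadherin gene Cdh8 (8.38-fold). Mpzl3 and Ccdc69 stood at 9.78 ± 2.48 and 7.93 ± 0.301 in NeuN+ and were listed at 0 in both NeuN- libraries, as was the small nuclear RNA Rnu12, whose NeuN+ level of 29.1 ± 27.7 was imprecise. Other large decreases were in Atp13a4 (31.5-fold), the tubulin glycylase gene Ttll3 (30.9-fold), Gsap (30.7-fold), the interferon-induced gene Ifi35 (30.6-fold), Rab29 (30.4-fold), Pipox (30.4-fold) and Tmprss5 (30.1-fold). The GABA transporter gene Slc6a13 stood at 28.1 ± 0.823 in NeuN- and was listed at 0 in both NeuN+ libraries. The largest limma adjusted p among these 20 genes was 9.2e-04.

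General neuronal genes rose as a list in cerebellar NeuN+: 17 of 19 were higher, 1 was lower and 1 did not pass (camera adjusted p = 2.8e-06, adjusted p = 0.0694 with an estimated correlation). The sodium channel gene Scn2a1 was 4.62-fold higher, the active zone gene Rims1 4.05-fold higher, and the neurofilament gene Nefl 1.85-fold lower. Granule cell genes had 14 of 16 higher, such as Grm4 (6.85-fold), Gabra6 (5.11-fold) and Fat2 (4.37-fold), and 2 lower, Zic4 (1.98-fold) and Zic5 (2.04-fold; camera adjusted p = 8.6e-05, adjusted p = 0.119 with an estimated correlation). Synaptic vesicle genes had 14 higher, 1 lower and 2 not passing (camera adjusted p = 2.7e-04, adjusted p = 0.216 with an estimated correlation), with Syt2 3.07-fold higher. Voltage-gated channel genes had 19 higher, 1 lower and 7 not passing (camera adjusted p = 9.3e-05, adjusted p = 0.0694 with an estimated correlation), with Kcnc1 5.32-fold higher.

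Glial lists fell in cerebellar NeuN+. All 19 astrocyte genes were lower, with Fgfr3 20.8-fold lower (camera adjusted p = 8.0e-09, adjusted p = 0.0621 with an estimated correlation), and all 19 oligodendrocyte genes, with the myelin genes Mag and Mbp 14.9-fold and 12.1-fold lower (camera adjusted p = 2.0e-08, adjusted p = 0.0694 with an estimated correlation). All 12 Bergmann glia genes were lower, including Gria1 (11.3-fold) and Gdf10 (5.39-fold; camera adjusted p = 1.2e-05, adjusted p = 0.0694 with an estimated correlation). Precursor genes had 11 of 12 lower, with Ptprz1 18.9-fold lower, and 1 higher (camera adjusted p = 8.2e-04, adjusted p = 0.0694 with an estimated correlation). Of 19 microglial genes, 15 were lower and 4 did not pass (camera adjusted p = 8.2e-04, adjusted p = 0.0694 with an estimated correlation), with Tyrobp 8.78-fold lower. Vascular genes had 1 higher, 7 lower and 1 not passing (camera adjusted p = 0.0159, adjusted p = 0.193 with an estimated correlation), a call lost without the filter on low values, and the 8 meningeal fibroblast genes were all lower (camera adjusted p = 0.00312, adjusted p = 0.119 with an estimated correlation). Cholesterol synthesis genes had 1 higher, 11 lower and 4 not passing of 16, with the sterol oxidase gene Msmo1 3.80-fold lower (camera adjusted p = 0.0153, adjusted p = 0.324 with an estimated correlation).

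The other 14 lists did not pass with camera in cerebellum (adjusted p in parentheses). Cerebellar inhibitory interneuron genes had 2 higher, 6 lower and 3 not passing (camera adjusted p = 0.176), with Sorcs3 4.47-fold lower, and Purkinje genes 8 higher, 2 lower and 4 not passing (0.0505), with Slc1a6 2.85-fold higher. Glutamate receptor genes had 7 higher, 8 lower and 1 not passing (0.757) and GABA-A receptor genes 5 higher, 5 lower and 3 not passing (0.757). Nuclear long RNAs had 4 higher, 1 lower and 3 not passing (0.215), with Meg3 2.42-fold higher and Neat1 26.99-fold lower. Cortical projection genes had 6 higher, 4 lower and 7 not passing (0.650), cortical interneuron genes 1 higher, 5 lower and 8 not passing (0.229), and forebrain transcription factors 0 higher, 1 lower and 10 not passing (0.988). Histone mark enzyme genes had 12 higher, 7 lower and 6 not passing (0.176), choroid plexus and ependymal genes 4 higher, 3 lower and 0 not passing (0.634), and red blood cell genes 2 higher, 0 lower and 5 not passing (0.229). Hindbrain transcription factors had 6 higher, 5 lower and 0 not passing (0.959), immediate early genes 6 higher, 1 lower and 3 not passing (0.0523), and heat shock genes 3 higher, 4 lower and 0 not passing (0.757). Adjusted over the list alone, 22 of the 26 lists had the same counts; general neuronal genes then had 18 higher, cortical projection genes 5 higher, red blood cell genes 1 higher and cholesterol synthesis genes 12 lower.

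**Figure D2:**
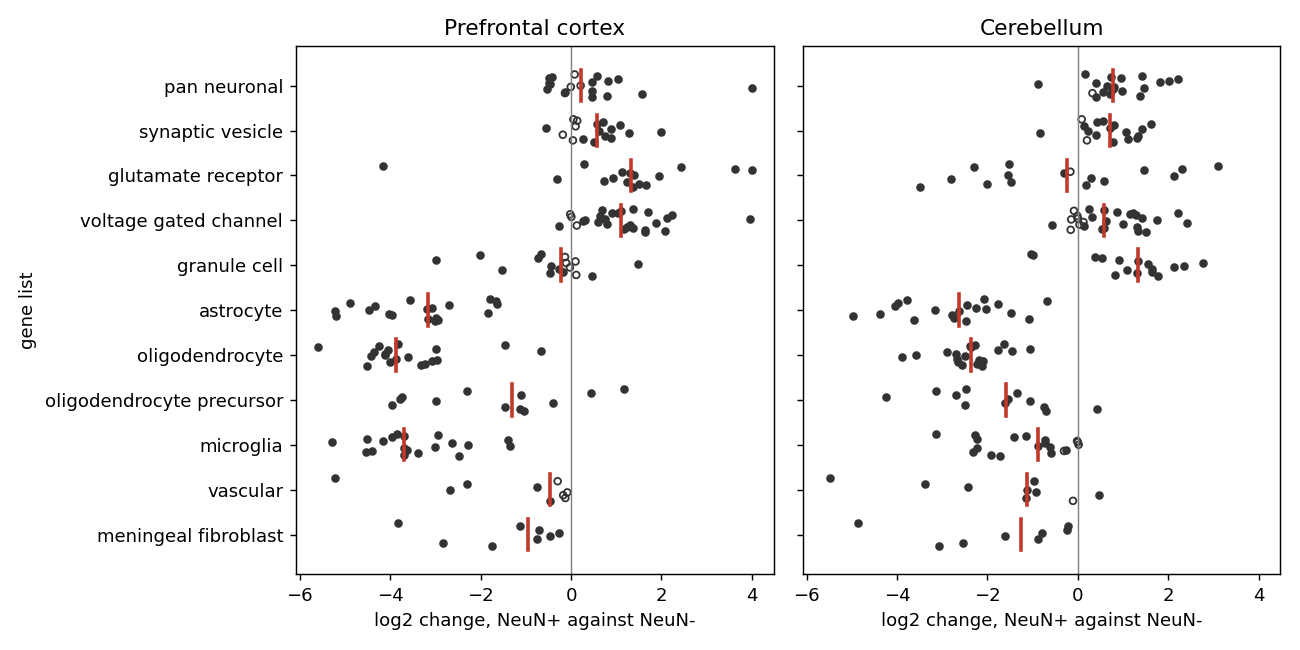
Log2 change of NeuN+ against NeuN- in prefrontal cortex and cerebellum for the genes of 11 lists, with 1 point per gene, filled where limma's adjusted p passed and open where it did not, and a red line at each list median. The median of the microglia list was -3.70 in prefrontal cortex and -0.87 in cerebellum, and that of the general neuronal list 0.21 and 0.77.

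In cerebellum limma with Benjamini-Hochberg adjustment called 10301 features, 4661 higher and 5640 lower in NeuN+, of which 1192 and 2470 changed by at least 2-fold. The higher share was 45.2% with the scaling used, 45.04% with unscaled FPKM, 55.8% with quantile normalization and 44.9% with a common sum, with medians of all features of -0.04, -0.04, 0.08 and -0.05. Ltbp2, Cdh8 and Ttll3 overlap other features and are uncertain. At 2-fold, 274 features were higher in NeuN+ in both regions, against 112 for independent lists, and 969 were lower in both, against 331. Opposite changes were found for 132 features higher in prefrontal cortex and lower in cerebellum, against 232, and for 56 features with the reverse, against 160. The comparisons share no libraries.

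The comparison of cerebellum with prefrontal cortex in NeuN+ nuclei asked how neuronal nuclei differ between the regions. Granule cell genes were higher in cerebellum. Gabra6, the GABA-A receptor subunit gene of granule cells (chromosome 11, 42119939 to 42134574, mm9), stood at 254 ± 4.25 in cerebellar NeuN+ (SD, n = 2) and was listed at 0 in both prefrontal NeuN+ libraries. Cbln1, which encodes a synapse-organizing protein of granule cells, was 131-fold higher, at 167 ± 4.13 against 0.286 ± 0.0561, and Pcp2, a Purkinje gene, was 172-fold higher, at 413 ± 3.78 against 1.40 ± 0.0276. The signalling regulator gene Rgs4 (chromosome 1, 171671608 to 171677773, mm9) was 218-fold lower, at 0.0313 ± 0.0122 against 224 ± 3.17, and the neuropeptide gene Sst 127-fold lower, at 5.40 ± 1.62 against 800.3 ± 60.8.

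Grin2c (109-fold), Cbln3 (51.2-fold), the transcription factor gene Neurod1 (50.1-fold), Il20rb (48.9-fold) and Stap2 (46.1-fold) were also higher in cerebellar NeuN+. Lhx1os, a noncoding RNA, and Crtam stood at 182 ± 8.45 and 121 ± 3.18 there and were listed at 0 in both prefrontal NeuN+ libraries. Lower in cerebellum were the kinase gene Plk2 (93.1-fold), Cpne6 (78.5-fold), the synaptotagmin gene Syt16 (54.8-fold) and Lamp5 (51.4-fold). Rasl10a, the neuropeptide gene Vip, Crym and Syt17 stood at 90.7 ± 0.532, 68.9 ± 1.77, 63.3 ± 1.72 and 47.5 ± 0.397 in prefrontal NeuN+ and were listed at 0 in both cerebellar NeuN+ libraries. The largest limma adjusted p among these 20 genes was 6.5e-07.

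All 16 granule cell genes were higher in cerebellar NeuN+ (camera adjusted p = 2.0e-08, adjusted p = 0.114 with an estimated correlation). Purkinje genes had 11 higher, 2 lower and 1 not passing of 14, with Car8 16.6-fold higher (camera adjusted p = 0.00106, adjusted p = 0.114 with an estimated correlation). Hindbrain transcription factors had 10 of 11 higher and 1 not passing, with Zic1 20.7-fold and En2 20.4-fold higher (camera adjusted p = 4.3e-05, adjusted p = 0.134 with an estimated correlation), and all 11 forebrain transcription factors were lower, with Emx1 at 11.5 ± 0.993 in prefrontal NeuN+ and listed at 0 in both cerebellar NeuN+ libraries (camera adjusted p = 2.4e-04, adjusted p = 0.187 with an estimated correlation). Cortical projection genes had 15 of 17 lower, including the transcription factor gene Mef2c (30.1-fold), and 1 higher, Neurod2 (3.83-fold; camera adjusted p = 4.3e-05, adjusted p = 0.114 with an estimated correlation). Cortical interneuron genes had 12 of 14 lower, including the tachykinin gene Tac1 (38.9-fold), and 1 higher, the vesicular GABA transporter gene Slc32a1 (2.46-fold; camera adjusted p = 4.3e-04, adjusted p = 0.114 with an estimated correlation).

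Glial and blood genes also differed between the NeuN+ groups. Astrocyte genes had 12 higher, 2 lower and 5 not passing of 19, with S100b 3.89-fold higher and Slc1a2 3.60-fold lower (camera adjusted p = 0.00395, adjusted p = 0.128 with an estimated correlation). Oligodendrocyte genes had 12 higher, 1 lower and 6 not passing of 19 (camera adjusted p = 0.00321, adjusted p = 0.208 with an estimated correlation), and red blood cell genes had 5 higher, 0 lower and 2 not passing of 7 (camera adjusted p = 0.00685, adjusted p = 0.150 with an estimated correlation). Microglial genes had 4 higher, 13 lower and 2 not passing of 19 (median -0.79) and did not pass (camera adjusted p = 0.0960). Histone mark enzyme genes had 17 higher, 2 lower and 6 not passing of 25, with Jarid2, a Polycomb cofactor gene, 2.90-fold higher and the deacetylase gene Hdac9 5.93-fold lower (camera adjusted p = 0.00569, adjusted p = 0.187 with an estimated correlation). Cholesterol synthesis genes had 3 higher, 11 lower and 2 not passing of 16 (camera adjusted p = 0.0269, adjusted p = 0.354 with an estimated correlation). Synaptic vesicle genes had 12 higher, 3 lower and 2 not passing of 17 (camera adjusted p = 0.0179, adjusted p = 0.363 with an estimated correlation), with the stricter filter ending the call. GABA-A receptor genes had 3 higher, 10 lower and 0 not passing of 13, with Gabra5 29.4-fold lower (camera adjusted p = 0.0336, adjusted p = 0.187 with an estimated correlation); their call was lost with the stricter filter and with only the 4 libraries compared. Adjusted over the list alone, 22 of the 26 lists had the same counts; Purkinje genes then had 12 higher, glutamate receptor genes 4 higher, voltage-gated channel genes 12 lower and cholesterol synthesis genes 12 lower.

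Limma with Benjamini-Hochberg adjustment called 11100 features between the NeuN+ groups, 5242 higher and 5858 lower in cerebellum, of which 1739 and 2710 changed by at least 2-fold. The higher share was 47.2% with the scaling used, 47.6% with unscaled FPKM, 53.9% with quantile normalization and 50.3% with a common sum. Pcp2 and Rasl10a overlap other features and are uncertain.

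The comparison of the regions in NeuN- nuclei asked how this gate, which is meant to hold glial nuclei, differs between them. Neuronal genes of each region were among the largest differences. Pcp2 (chromosome 8, 3623371 to 3625545, mm9) stood at 388 ± 21.5 in cerebellar NeuN- and 2.87 ± 1.17 in prefrontal NeuN- (SD, n = 2), 103-fold higher, and Lhx1os was 140.0-fold higher. Sst was 141-fold lower in cerebellum, at 7.39 ± 2.35 against 1156 ± 67.6, and the neuropeptide gene Cck 38.9-fold lower. The cathepsin S gene Ctss of microglia (chromosome 3, 95330708 to 95360327, mm9) was 39.3-fold lower, at 3.35 ± 0.544 against 169 ± 0.156.

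Other genes higher in cerebellar NeuN- were the myosin-binding gene Mybpc1 (61.9-fold), Ttll3 (42.9-fold), Cbln1 (38.1-fold), Gabra6 (36.4-fold), the matrix gene Abi3bp (36.2-fold), Cd70 (24.0-fold) and the kinase gene Mapk13 (22.8-fold). The haemoglobin gene Hbb-bs stood at 27.02 ± 12.7 in cerebellar NeuN- and belongs to a cluster of near-identical copies, so its value is uncertain. Lower in cerebellar NeuN- were Lamp5 (79.9-fold), Crym (68.2-fold), Vip (53.8-fold), Syt5 (37.1-fold), Rprml (33.7-fold) and Mal2 (28.8-fold). Rasl10a stood at 30.8 ± 0.0335 in prefrontal NeuN- and was listed at 0 in both cerebellar NeuN- libraries. The largest limma adjusted p among these 20 genes was 1.1e-05.

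All 19 microglial genes were lower in cerebellar NeuN-, with P2ry12 and P2ry13 22.0-fold and 28.0-fold lower (median -2.75, camera adjusted p = 2.9e-07, adjusted p = 0.0890 with an estimated correlation). Granule cell genes had 15 higher, 1 lower and 0 not passing of 16, with Neurod1 21.3-fold higher (camera adjusted p = 3.2e-05, adjusted p = 0.169 with an estimated correlation), and Purkinje genes 12 higher, 1 lower and 1 not passing of 14 (camera adjusted p = 0.00177, adjusted p = 0.169 with an estimated correlation). All 11 hindbrain transcription factors were higher, with Tfap2b 12.9-fold higher (camera adjusted p = 4.4e-05, adjusted p = 0.169 with an estimated correlation), and all 11 forebrain transcription factors were lower, with Emx1 10.9-fold lower (camera adjusted p = 8.7e-04, adjusted p = 0.234 with an estimated correlation). Cortical projection genes had 16 of 17 lower, including the kinase gene Itpka (11.1-fold), and 1 higher (camera adjusted p = 9.7e-05, adjusted p = 0.159 with an estimated correlation). Glutamate receptor genes had 11 higher, 3 lower and 2 not passing of 16, with Gria1 7.28-fold higher (camera adjusted p = 0.0363, adjusted p = 0.229 with an estimated correlation), and histone mark enzyme genes 17 higher, 4 lower and 4 not passing of 25, with Hdac4 3.01-fold higher (camera adjusted p = 0.0320, adjusted p = 0.245 with an estimated correlation); the stricter filter ended both calls.

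Astrocyte and oligodendrocyte genes moved both ways and did not pass as lists with camera (adjusted p in parentheses). Astrocyte genes had 9 higher, 7 lower and 3 not passing of 19 (camera adjusted p = 0.639), with Gja1 3.65-fold lower, and oligodendrocyte genes 5 higher, 12 lower and 2 not passing of 19 (0.177), with Ugt8a 5.01-fold lower. Bergmann glia genes had 8 higher, 3 lower and 1 not passing of 12 (0.0597), with Gdf10 10.4-fold and Vim 11.8-fold higher. General neuronal genes had 4 higher, 13 lower and 2 not passing of 19 (0.0519), with Snap25 3.63-fold lower. Adjusted over the list alone, 24 of the 26 lists had the same counts; astrocyte genes then had 10 higher and precursor genes 7 lower.

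Limma with Benjamini-Hochberg adjustment called 11422 features between the NeuN- groups, 5822 higher and 5600 lower in cerebellum, of which 2079 and 2514 changed by at least 2-fold. The higher share was 51.0% with the scaling used, 42.6% with unscaled FPKM, 53.2% with quantile normalization and 62.1% with a common sum, with medians of all features of 0.02, -0.13, 0.07 and 0.30. Pcp2, Ttll3, Rasl10a and Hbb-bs overlap other features and are uncertain. At 2-fold, 697 features were higher in cerebellum in both gates, against 251 for independent lists, 1157 lower in both, against 474, and 51 and 133 changed in opposite directions (higher or lower in NeuN+, respectively), against 304 and 391.9. These comparisons also share no libraries.

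The last comparison tested whether the gate change itself differed between the regions. Positive values mean a NeuN+ against NeuN- change that was higher in cerebellum. Grin2c (chromosome 11, 115110483 to 115128557, mm9) had the largest positive value among genes passing the naming rule, 7.25 on the log2 scale (SE 0.0696): it was lower in NeuN+ in prefrontal cortex, at 0.259 ± 0.0178 against 21.4 ± 0.683 (SD, n = 2), and higher in NeuN+ in cerebellum, at 137 ± 0.157 against 15.0 ± 0.438. P2ry12 had 5.28 (SE 0.202), from levels of 3.88 ± 1.1 and 3.82 ± 0.30 in the cerebellar gates. Abi3bp (chromosome 16, 56477959 to 56690248, mm9) had the largest negative value among them, -6.34 (SE 0.0885), at 5.89 ± 0.264 and 0.252 ± 0.0289 in prefrontal NeuN+ and NeuN- and at 2.07 ± 0.0174 and 44.3 ± 0.139 in cerebellum. The collagen gene Col6a1 had -5.67 (SE 0.159). The largest limma adjusted p among the 20 genes named for this comparison was 1.6e-04.

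**Figure D3:**
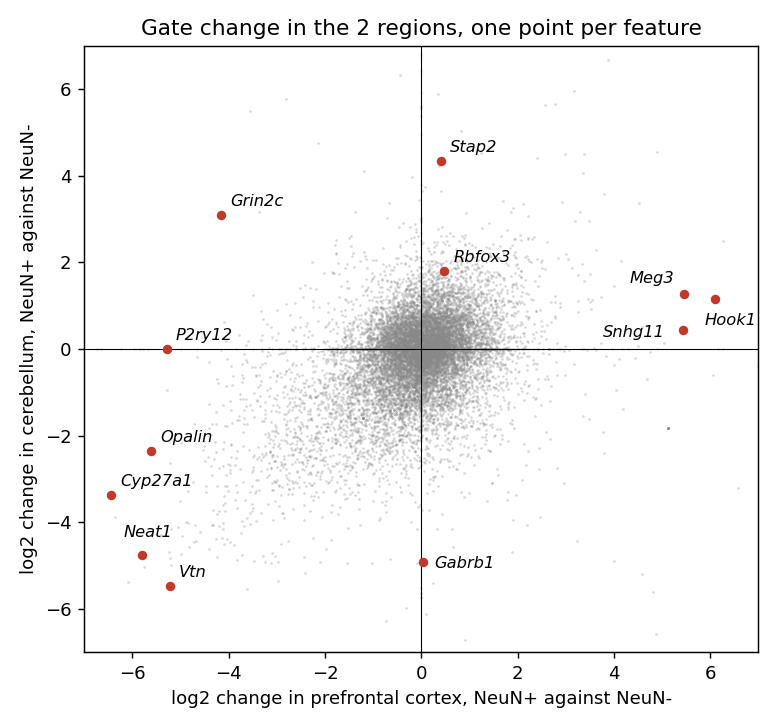
Log2 change of NeuN+ against NeuN- in prefrontal cortex (x axis) and cerebellum (y axis), with 1 grey point per feature and named genes in red; 30 features lie beyond the axes, which end at 7. Grin2c fell in prefrontal cortex (-4.15) and rose in cerebellum (3.10), while Neat1 fell in both (-5.80 and -4.75).

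All 19 microglial genes had a positive difference (median 2.28, camera adjusted p = 6.2e-07, adjusted p = 0.0970 with an estimated correlation). Granule cell genes had 14 of 16 positive, with the transcription factor gene Pax6 at 3.90 (camera adjusted p = 2.3e-05, adjusted p = 0.170 with an estimated correlation), and oligodendrocyte genes 16 of 19, with Opalin at 3.25 (camera adjusted p = 9.5e-05, adjusted p = 0.170 with an estimated correlation). General neuronal genes had 13 positive, 3 negative and 3 not passing, with Snap25 at 1.45 and Grin1 at -2.55 (camera adjusted p = 0.00331, adjusted p = 0.170 with an estimated correlation). Astrocyte genes had 11 positive and 2 negative of 19, with Gja1 at 2.61 (camera adjusted p = 0.0238, adjusted p = 0.170 with an estimated correlation), and red blood cell genes 4 positive of 7 (camera adjusted p = 0.0264, adjusted p = 0.172 with an estimated correlation). The astrocyte call was lost with quantile normalization, and the red blood cell call with that, without scaling and without the filter.

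Glutamate receptor genes had 13 of 16 negative, with Gria1 at -4.86 and Grin2b at -4.73, and 1 positive, Grin2c (camera adjusted p = 5.4e-04, adjusted p = 0.170 with an estimated correlation). Nuclear long RNAs had 7 of 8 negative, counting Malat1 (listed at 0 as above), with Snhg11 at -4.98 and Meg3 at -4.18, and Neat1 positive (camera adjusted p = 0.00331, adjusted p = 0.170 with an estimated correlation). Cerebellar inhibitory interneuron genes had 8 of 11 negative, with Kit at -1.65 (camera adjusted p = 0.0238, adjusted p = 0.172 with an estimated correlation). Cortical interneuron genes had 9 negative, 1 positive and 4 not passing, with Adarb2 at -2.81 (camera adjusted p = 0.0264, adjusted p = 0.170 with an estimated correlation), and lost the call without prefrontal NeuN+ replicate 2 (list median -0.76). Adjusted over the list alone, 24 of the 26 lists had the same counts; general neuronal genes then had 14 positive and immediate early genes 2 negative.

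Limma with Benjamini-Hochberg adjustment called 10076 features, 4757 with a positive and 5319 with a negative difference. The positive share was 47.2% with the scaling used, 57.6% with unscaled FPKM, 51.2% with quantile normalization and 37.3% with a common sum, with medians of all features of -0.06, 0.13, 0.02 and -0.28.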

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

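The gate change differed between cerebellum and prefrontal cortex, by the interaction term of limma with Benjamini-Hochberg adjustment, for 10076 of 14376 features. Camera called 10 gene lists at the preset correlation and 0 with an estimated correlation (adjusted p from 0.0970 to 0.172 for those 10). Of 76 different genes named for the largest changes, 70 passed the limma interaction test, 37 with a positive and 33 with a negative difference. The 20 genes named for the difference itself were selected by that test, and most features passed it, so this count is a description only. The values below are log2 differences, cerebellum minus prefrontal cortex, and for genes listed at 0 in a group they depend on the pseudocount. The explanations below and their tests were chosen after the results were seen; the predictions for ribosomal protein genes, like those for gene span further on, were written before their values were computed.

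List medians were 0.69 for general neuronal genes, 1.54 for granule cell genes, 0.36 for astrocyte genes, 1.36 for oligodendrocyte genes, 2.28 for microglial genes and 1.77 for red blood cell genes. They were -0.82 for cortical interneuron genes, -0.77 for cerebellar inhibitory interneuron genes, -1.72 for glutamate receptor genes and -2.30 for nuclear long RNA genes.

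Among genes named in the prefrontal gate comparison, the difference was 5.28 for P2ry12, 4.35 for Plcd4, 3.25 for Opalin, 3.06 for Cyp27a1, 2.61 for Gja1, 2.49 for Lpar6, 2.47 for Tmem63a, 1.11 for Hapln2, 1.04 for Neat1 and 0.39 for Litaf. Negative differences were -4.98 for Pip5kl1, -4.98 for Snhg11, -4.95 for Hook1, -4.64 for Frmpd3, -4.33 for Epha10, -4.18 for Meg3, -3.97 for Kcnh7, -3.82 for Kalrn, -2.55 for Grin1 and -2.10 for Ipw. Among genes named in the cerebellar gate comparison, it was 7.25 for Grin2c, 4.53 for Ccdc69, 4.19 for Ptpn22, 3.95 for Stap2, 3.67 for Ltbp2, 3.64 for Il20rb, 1.72 for Mpzl3, 1.37 for Epha3 and 0.85 for Cdh8, and -4.96 for Gabrb1, -4.86 for Ttll3, -3.38 for Ifi35, -2.81 for Tmprss5, -1.96 for Rab29, -1.82 for Gsap, -1.68 for Pipox and -1.04 for Slc6a13. Genes named between the NeuN+ groups had 3.62 for Crtam, 2.81 for Gabra6, 1.82 for Cbln3, 1.78 for Cbln1, 1.23 for Neurod1, 0.75 for Pcp2, 0.64 for Lamp5 and 0.38 for Lhx1os. The lower ones had -5.08 for Plk2, -3.50 for Rgs4, -3.24 for Cpne6, -2.73 for Syt16, -2.67 for Syt17, -1.53 for Rasl10a and -0.38 for Vip. Genes named between the NeuN- groups had 4.10 for Ctss, 1.20 for Cck, 1.06 for Mal2, 0.67 for Syt5 and 0.30 for Rprml, and -6.34 for Abi3bp, -4.77 for Mybpc1, -3.28 for Cd70 and -2.89 for Mapk13. Genes named for the difference itself had 4.75 for Tmem51, 4.48 for Hmga2-ps1, 4.25 for Cd68, 4.22 for Lyn and 4.19 for Hspb6, and -5.67 for Col6a1, -5.33 for Rpph1, -5.27 for Socs2 and -5.25 for Syt10. Tmem51, Hmga2-ps1 and Lyn overlap other features, Hmga2-ps1 is a transcribed pseudogene and Rpph1 is the small RNA of RNase P, so these values are uncertain.

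In the prefrontal NeuN- libraries, general neuronal genes stood at 86.3% of their NeuN+ level by the list median, 41 glutamate receptor and voltage-gated channel genes at 42.6%, and 6 nuclear long RNAs (without Neat1 and Malat1, left out after their values were seen) at 13.4%. Neuronal nuclei like those of the NeuN+ gate would bring all alike if glial nuclei lacked these messages. Receptor and channel genes differed from general neuronal genes by 1.02 on the log2 scale (permutation test of genes, two-sided p = 6.2e-04). The difference was 2.69 for nuclear RNAs. The receptor and channel value argues against such nuclei as the whole source, although these values were known when the test was set. It does not exclude neurons of another make-up in the gate or glial nuclei that hold these messages. The nuclear RNA value decides nothing, because its set was reduced after its values were seen. The general neuronal difference between the regions was at least 0.50 under 4 scalings, so none of these scalings accounts for it. They moved the median difference of all features only between -0.28 and 0.13. The prefrontal gate change of these genes (list median 0.21) was not tested in this way. The median of all features there ran from -0.19 to 0.17 with the scaling, so the 86.3% depends on it. Ribosomal protein genes lay at -0.49 relative to all features, at percentile 0.25 of 10000 random lists matched on level, the direction that cytosolic or free RNA carried into the NeuN- libraries would give, so this remains a candidate explanation. In cerebellum the differences were -0.49 for receptor and channel genes (permutation test of genes, two-sided p = 0.0712) and -0.24 for nuclear RNAs. The latter decides nothing either. General neuronal genes stood at 58.5% of NeuN+, and neuronal nuclei remain a candidate there. The comparison addresses only nuclei like those of the NeuN+ gate, not neurons of another make-up. Cerebellar inhibitory interneuron genes, for example, had 2 higher, 6 lower and 3 not passing in cerebellar NeuN+ (camera adjusted p = 0.176). The -0.49 lies close to a bound set after the values were seen. It pools glutamate receptor genes (list median -0.24), among them Gria1 of the Bergmann glia list, with channel genes (0.58). Ribosomal protein genes lay at 0.23 (percentile 78.6), without the drop predicted for cytosolic or free RNA carried into NeuN-. This does not exclude such RNA, since cell types can differ in these genes and both gates can carry it. Glial nuclei that differ in these messages and biological differences between the regions stay open and were not tested, and genes are not independent replicates.

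Microglial genes had a median log2 change of -2.75 from prefrontal to cerebellar NeuN- libraries, against -0.28 for 38 astrocyte and oligodendrocyte genes. A lower share of glial nuclei would lower all of them alike, but the medians differed by -2.47 (permutation test of genes, two-sided p = 1e-05, the smallest that 100000 permutations can give). The microglial median was -2.59 or lower under 4 scalings, which argues against library scaling. Fewer microglia in cerebellum, lower expression in them and a selective loss of their nuclei during isolation stay open and were not tested.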

How the results depend on the processing

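The alternatives were planned, except those for Rbfox3 and the one without small RNAs, which were chosen after seeing the data. Counts of genes called stayed within 1.5 times the reported counts under every setting run. With 1 library left out, they ran from 9405 to 10276 in the prefrontal gate comparison, 9272 to 10305 in the cerebellar one, 10278 to 11049 between the NeuN+ groups, 10611 to 11293 between the NeuN- groups and 9358 to 9605 for the difference between the regions; the lone library left in a group is then assumed to vary like the others. Counts of lists called by camera ran from 12 to 15, 12 to 13, 13 to 14, 8 to 10 and 9 to 10. Rbfox3 kept its direction and its call under all settings, with log2 changes of 0.38 to 0.56 in prefrontal cortex and 1.79 to 1.85 in cerebellum with 1 library left out.

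With an estimated correlation, camera called 3, 0, 0, 0 and 0 of the 26 lists in the 5 comparisons, in the order above, against 13, 12, 13, 8 and 10; fry, which tests another question, called 26, 23, 24, 25 and 19. The replicate agreement, a mean Spearman correlation of 0.975, was 0.968 with the filter at FPKM 5, possibly because fewer features at 0 or near it were left, which was not tested. Of 587 log2 changes of 284 named genes, 5 changed sign, in 6 instances: Dusp1 in prefrontal cortex with a common sum (0.0218), Etv1 between the NeuN- groups with quantile normalization (0.0337) and a common sum (0.108), and with a pseudocount of 0.1 the differences between the regions of Lum (-0.0175), Syt2 (-0.0579) and Zic5 (0.0838). The cause was not tested. In the same direction, named genes lost their call 47 times with 1 library left out and 40 times under other settings, and lists 4 and 70 times, most of the latter with an estimated correlation.

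With the replicate number as a block, 10343, 10183, 11021, 11373 and 9952 genes were called. The numbers are not known to pair libraries: deviations of same-numbered libraries from their group means correlated between -0.045 and 0.034. Leaving out short features had been planned and was not run because the tables give no lengths. Depth limits low genes: small changes of low genes can be missed, and a value of 0 is no proof of absence.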

Other observations

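The 3 gene families and the hypothesis below were chosen after the gene results were seen. In prefrontal NeuN+ libraries, 70 of 79 genes for oxidative phosphorylation were lower and 1 was higher than in NeuN-, with a median log2 change of -0.66 (-0.89 to -0.36 over 4 scalings). Of 80 ribosomal protein genes, 58 were lower and 3 higher, with a median of -0.50 (-0.74 to -0.26 over 4 scalings). In cerebellum, 47 oxidative phosphorylation genes were higher and 5 lower, with a median of 0.33 (0.26 to 0.33 over 4 scalings), and 36 ribosomal protein genes were higher and 10 lower, with a median of 0.19 (0.16 to 0.19 over 4 scalings). The median difference of the gate change between the regions was 0.98 (0.63 to 1.21 over 4 scalings) for oxidative phosphorylation and 0.71 (0.45 to 0.94 over 4 scalings) for ribosomal protein genes.

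Between the NeuN+ groups, 58 oxidative phosphorylation and 61 ribosomal protein genes were higher in cerebellum, with medians of 0.81 (0.77 to 0.90 over 4 scalings) and 0.64 (0.64 to 0.73 over 4 scalings). Between the NeuN- groups both medians changed sign with the scaling, at -0.10 (-0.33 to 0.20 over 4 scalings) and 0.01 (-0.21 to 0.35 over 4 scalings). Of 20 clustered protocadherin genes, whose products take part in neuronal self-recognition, 11 were higher and 6 lower in prefrontal NeuN+, with a median of 0.40 (0.26 to 0.72 over 4 scalings), and 10 higher and 4 lower in cerebellar NeuN+, with a median of 0.32 (0.32 to 0.70 over 4 scalings). Their median difference between the regions was 0.01 and changed sign with the scaling; protocadherin genes share exons, so their FPKM are uncertain.

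A hypothesis was that neuronal genes with a long span gain in NeuN+ against NeuN- where unspliced nuclear RNA is counted, and its predictions were written before the correlations were computed. Across 155 genes of the neuronal lists, the log2 change in prefrontal cortex rose with the gene's span (Spearman's rho 0.37, permutation p = 2e-05, adjusted p = 4e-05 over both regions; Pearson's r 0.31, permutation p = 6e-05; two-sided, 100000 permutations). In cerebellum no relation was found (rho -0.0248, permutation p = 0.759, adjusted p = 0.759; r -0.11, permutation p = 0.185). Genes are not independent replicates. The prefrontal value has the direction predicted for more unspliced RNA of long genes in NeuN+ nuclei. The genes pool lists whose prefrontal medians differed, such as glutamate receptor (1.34) and general neuronal genes (0.21). Whether these lists differ in span was not tested, nor was RNA carried into the NeuN- libraries. In cerebellum the predicted rise was not found. The set there includes cortical projection and interneuron genes (list medians 0.04 and -0.10), so the value does not decide the question. The share of intronic reads was not analysed here.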
